A study of Brevibacterium linens with 3 samples.

How the data were processed

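Messenger RNA profiles of Brevibacterium linens BS258 were compared between 3 calcium levels, 0, 50 and 150 mM calcium chloride for 24 h, with 1 library per level. Per the labels' protocols, total RNA was extracted with a bacterial RNA kit that includes DNase I, 3 µg of it entered each library, and libraries followed standard Illumina protocols. Bowtie2 2.2.3 and HTSeq 0.6.1 are named in the submitters' processing notes. The genome build, the annotation, strandedness and the removal of ribosomal RNA are not given in the sources used here. The authors deposited 1 table per library with a locus tag and its FPKM, the unit named in the file headers; FPKM divides a gene's fragments by its length and by the library's total, and so removes depth but not differences in composition between libraries.

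No reference genome or table of gene names was used here, and the tables do not pair the tags with names. The 33 gene lists fixed before the data were examined, which select genes by product name or symbol, and their planned comparison with 10000 random lists could therefore not be run, and urease, ion transport and other pathways are not analysed here. The design had foreseen count data or FPKM, and its FPKM form was followed. For each pair of libraries the log2 ratio of FPKM + 1 was computed per tag; folds quoted for single tags are plain ratios of FPKM. The pseudocount lowers the log2 ratio of tags with low values. A tag was listed as higher or lower by size alone, with an absolute log2 ratio of at least 1 and a mean over the 3 libraries of at least 5 FPKM; with 1 library per level there is no test, and a rule of size also passes differences that replicate cultures could show by chance. The rule for named tags, also fixed before the data were examined, takes the 2 highest and the 2 lowest log2 ratios of each comparison when no gene names can be matched.

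Depth was recovered from the FPKM values, a step added after the data were seen. Ratios of low values between libraries were ratios of small whole numbers times 1 constant per pair, which gave the relative depths, and the common step of the gene lengths gave the totals. The recovered totals of 3733619, 3527370 and 3793953 fragments each lay within 5.1e-05 of a whole number. For each tag the smallest whole length from 60 to 30000 bases was then taken at which all 3 libraries held whole fragments, within 1e-06 fragments or a relative 2e-09. All 3382 tags with a value above 0 had such a length, with a median of 831 bases, and 95.5% of the lengths were multiples of 3. With 2 of the totals shifted by 0.1%, 0.517% of the 2126 tags with at least 300 fragments had one. The smallest solution can be a whole divisor of the true count, so fragments per tag are lower limits and their intervals the widest that the values allow; summed over tags they came to 94.2%, 94.9% and 94.4% of the totals. In simulated data with known lengths and totals (3422 tags), all 3 totals were recovered, 90.1% of the lengths were exact and 100% were the true length or a divisor of it, and 95.0% of the fragments of the poorest library were accounted for. Counting intervals of a ratio are exact 95% Clopper-Pearson intervals of one library's share of a tag's fragments in both libraries, scaled by the totals; fragments amplified by PCR are not independent molecules, and the intervals leave out the spread between cultures. No count model was applied, because the deposited unit is FPKM.

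The same simulation covered 50 against 0 mM (3422 tags, Poisson counts). The rule of size found 100% of 50 tags at 4-fold and of 50 tags at 3-fold. It also found 96.0% of 50 tags at a fold of 0.25 and of 50 at 0.33, and 0.031% of 3222 unchanged tags. The changed tags were drawn only from those with at least 50 expected fragments, and every simulated fold lay beyond the rule of size. High shares were therefore largely built in. Shares were also not split by abundance, so they do not give the sensitivity over all tags. The 3222 are all unchanged tags, not only those above the floor. Poisson counts leave out the spread between cultures, so 0.031% reflects counting error alone. Overlap of the comparisons that share the 0 mM library was set against 100 simulations of unchanged libraries with normal noise on the log2 scale. Runs of at least 4 successive tags in tag-number order were compared with 1000 shuffles of the order. Alternatives were median-of-ratios and equal-sum scaling, a pseudocount of 0.1, no floor, a floor of 20 FPKM and a 4-fold rule, and, added after the data were seen, a floor of 20 recovered fragments and a counting interval that excludes 1. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.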

Results

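The transcriptome of Brevibacterium linens BS258, a bacterial strain studied for the precipitation of calcium carbonate, was measured by RNA sequencing after 24 h in 0, 50 or 150 mM calcium chloride. Each calcium level is represented by 1 library, so the 3 libraries give differences between cultures with no replicate check, and no p-value or standard error is attached to any of them. The deposited tables list FPKM values (fragments scaled by gene length and library total) for the same 3422 locus tags in each library. The tags are the only identifiers in the tables and are not paired there with gene names, so genes are given by tag and no pathway is named. Totals recovered from the FPKM values were 3733619 fragments at 0 mM, 3527370 at 50 mM and 3793953 at 150 mM. The median tag held 358, 235 and 348 fragments in these libraries, respectively, which sets the counting precision of the values below. A value of 0 was listed for 58 tags at 0 mM, 86 at 50 mM and 57 at 150 mM, of which 40 were at 0 in all 3 libraries. A count of 0 allows an expected count of up to 3 fragments. Counting intervals and this limit cover counting error only, not the spread between cultures.

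Abundance was unevenly spread over the tags, most of all at 50 mM. Shares of fragments rest on the smallest gene lengths that the values allow and are lower limits. The 10 most abundant tags held 8.90% of the fragments at 0 mM, 13.0% at 50 mM and 6.92% at 150 mM. The number of tags that together held 50% of the fragments was 285 at 0 mM, 193 at 50 mM and 276 at 150 mM. The tags of highest mean level, singled out after their values were seen, were A2T55_RS12915 and A2T55_RS08920. A2T55_RS12915 (recovered length 378 bases) stood at 53372 FPKM at 0 mM, 95355 at 50 mM and 8420 at 150 mM, or 2.02%, 3.60% and 0.318% of all fragments. A2T55_RS08920 (369 bases) stood at 41676, 90194 and 19745 FPKM, or 1.54%, 3.33% and 0.729%.

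The comparison of 50 with 0 mM asks which genes differ in level when calcium is added. Of 3242 tags with a mean of at least 5 FPKM, 369 (11.4%) were at least 2-fold higher and 924 (28.5%) at least 2-fold lower at 50 mM, on the scale of log2(FPKM + 1). The higher tags together held 9.62% of the fragments at 0 mM and 28.2% at 50 mM, and the lower tags 27.1% and 6.98%. A2T55_RS02750 was the highest, at 12.5 FPKM (19 fragments) at 0 mM and 817 FPKM (1176 fragments) at 50 mM, a 65.5-fold higher level with a 95% exact counting interval of 41.8 to 109. A2T55_RS03655 was 54.2-fold higher (interval 38.0 to 80.0), going from 9.61 to 520 FPKM. At the low end, A2T55_RS00275 stood at 579 FPKM (2770 fragments) at 0 mM and 3.98 FPKM (18 fragments) at 50 mM, 145-fold lower with an interval of 91.8 to 246. A2T55_RS13330 was 166-fold lower (80.3 to 413), from 278 FPKM to 1.68 FPKM on 7 fragments. The order of these tags depends on the pseudocount: their log2 ratios were -6.86 and -6.70 with a pseudocount of 1, and -7.15 and -7.29 with 0.1. The counting interval excluded a ratio of 1 for 358 of the 369 higher tags and 909 of the 924 lower ones. These tags were chosen by size from the same fragments, with a median over tags of 296 mean fragments. Exclusion of 1 was therefore largely built in and adds no separate support.

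The excess of lower tags at 50 mM depended on the scaling of the libraries. The median log2 ratio of 50 over 0 mM was -0.36, with an interquartile range of -1.19 to 0.38, whereas that of 150 over 0 mM was -0.02. When the libraries were rescaled by the median of ratios, which brought the median tag to 0.01, 593 tags were higher and 656 lower at 50 mM, and the higher tags made up 47.5% of those at least 2-fold apart in place of 28.5%. Scaling the libraries to equal sums of FPKM moved the balance the other way, to 313 higher and 1015 lower tags at 50 mM. The lower median was found among the less abundant tags. With the 3242 tags divided into 4 equal bins by mean FPKM, the median log2 ratio of 50 over 0 mM was -0.70 in the lowest bin, -0.59 and -0.30 in the middle bins and 0.07 in the highest. The same medians for 150 over 0 mM were -0.02, -0.12, 0.02 and 0.03.

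**Figure D1:**
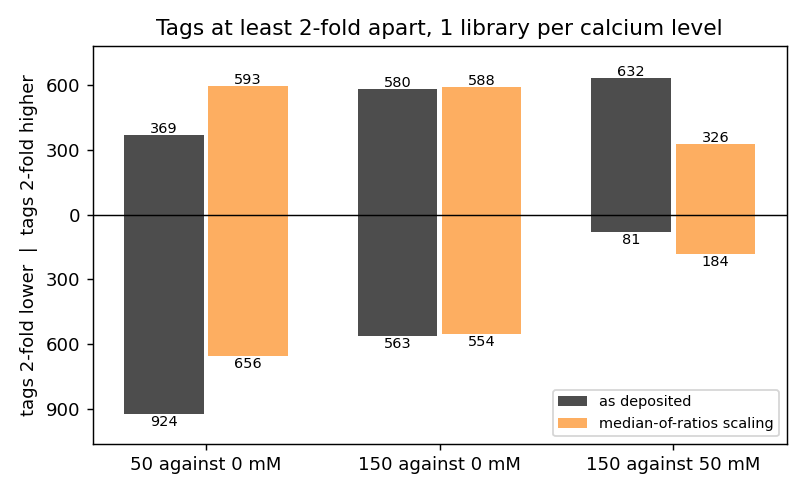
Numbers of locus tags at least 2-fold higher (bars above 0) and lower (bars below 0) in each comparison, among 3242 tags with a mean of at least 5 FPKM; grey bars use the deposited FPKM and orange bars the values after median-of-ratios scaling. The balance of higher and lower tags changes with the scaling in both comparisons that include the 50 mM library (369 and 924 become 593 and 656; 632 and 81 become 326 and 184) and hardly moves for 150 against 0 mM.

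At 150 mM against 0 mM, 580 tags (17.9%) were at least 2-fold higher and 563 (17.4%) at least 2-fold lower. Rescaling by the median of ratios left 588 higher and 554 lower. The higher tags held 8.92% of the fragments at 0 mM and 30.3% at 150 mM, and the lower tags 31.3% and 9.28%. The highest tag was again A2T55_RS02750, at 1151 FPKM (1781 fragments), 92.3-fold above its level at 0 mM (interval 58.9 to 154). A2T55_RS02740 stood at 15.5 FPKM at 0 mM and 1206 FPKM at 150 mM, 77.8-fold higher (54.0 to 117). It was level with A2T55_RS03655, which was 80.6-fold higher (56.6 to 119); both had a log2 ratio of 6.19 with a pseudocount of 1, and with 0.1 the ratios were 6.27 and 6.32. At the other end, A2T55_RS00275 was at 10.9 FPKM (53 fragments), 53.1-fold lower than at 0 mM (40.5 to 71.1). A2T55_RS02475 was 32.5-fold lower (27.3 to 38.9), at 446 FPKM at 0 mM and 13.7 FPKM at 150 mM. The interval excluded a ratio of 1 for 568 of the higher and 556 of the lower tags, which again were chosen by size from the same fragments.

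The libraries at 50 and 150 mM lay closer to each other than either did to the library at 0 mM. The SD of the log2 ratio across tags was 1.36 for 50 against 0 mM, 1.26 for 150 against 0 mM and 0.77 for 150 against 50 mM. At 150 mM, 632 tags were at least 2-fold higher and 81 at least 2-fold lower than at 50 mM, which became 326 and 184 after median-of-ratios scaling. Apart from A2T55_RS12915, the 2 highest and the 2 lowest tags of this comparison rested on few fragments. A2T55_RS12110 and A2T55_RS08350 were listed at 0 at 50 mM and held 6 fragments each at 150 mM (21.7 and 21.4 FPKM). A2T55_RS08760, the lowest, held 3 fragments at 50 mM and was listed at 0 at 150 mM. Their recovered lengths were short, at 73, 74 and 73 bases, respectively. Among tags with a mean of at least 20 fragments, a limit set after the data were seen, A2T55_RS00145 was 13.0-fold higher at 150 mM (3.08 against 40.2 FPKM, interval 7.08 to 26.6) and A2T55_RS01125 10.6-fold higher (9.54 against 101 FPKM, interval 6.77 to 17.4). A2T55_RS12915, the most abundant tag, was 11.3-fold lower at 150 than at 50 mM (11.1 to 11.5). It was among the 2 lowest without this limit too, with a log2 ratio of -3.50 on 127141 fragments at 50 mM and 12075 at 150 mM. A2T55_RS15580 was 5.57-fold lower (5.40 to 5.75), at 6775 and 1217 FPKM.

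Many tags were on the same side of 0 mM at both calcium levels. At least 2-fold higher levels at both 50 and 150 mM were found for 303 tags and at least 2-fold lower levels at both for 461. Both comparisons use the same library at 0 mM, so some overlap arises without any effect. Simulated unchanged libraries, each with an SD of 0.54 on the log2 scale (the spread that would account for all of the difference between the 50 and 150 mM libraries), gave on average 102 tags higher and 98.9 lower at both levels, with at most 128 and 127 in 100 simulations. They leave out the lower median at 50 mM: their lists at 1 level averaged 317 higher and 313 lower tags, against 369 and 924 observed at 50 mM, so the 461 lower tags have no like value in them. Independent lists of the observed sizes would share 66.0 higher and 160.5 lower tags. The covariance across tags of the 2 log2 ratios was 1.43, against 0.295 in the simulations, and Pearson's r across tags was 0.83 against 0.50. The observed values follow from the SDs of the log2 ratios given above, and the simulated values from the SD put in. They restate how close the 50 and 150 mM libraries lay to each other and add no separate evidence of a shared response. Tags are not independent replicates, and with 1 library at 0 mM the controls could not be split. The simulations give the 0 mM library the same noise as the others and do not cover a 0 mM culture that deviated more. Part or all of the excess may therefore come from the shared library.

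Part of these tags also stood at least 2-fold apart between the libraries at 50 and 150 mM. Of the 303 tags higher at both levels, 45 were at least 2-fold higher at 150 than at 50 mM and 10 at least 2-fold lower. Of the 461 tags lower at both levels, 116 were at least 2-fold higher at 150 than at 50 mM, nearer to the level at 0 mM, and 10 were lower still. Of all 924 tags at least 2-fold lower at 50 mM, 453 lay within 2-fold of 0 mM at 150 mM, as did 63 of the 369 tags higher at 50 mM. Tags listed by their level in the single 50 mM library can lie nearer to 0 mM in another library through that choice alone. After median-of-ratios scaling, 22 and 20 of 414 tags higher at both levels and 67 and 15 of 393 tags lower at both levels were 2-fold higher and lower, respectively, at 150 than at 50 mM. On that scale, 259 of 656 tags lower at 50 mM and 174 of 593 tags higher at 50 mM lay within 2-fold of 0 mM at 150 mM. The imbalance between the directions was thus smaller after scaling. Opposite differences of at least 2-fold were rare, and their balance turned with the scaling. As deposited, 3 tags (A2T55_RS08920, A2T55_RS15580 and A2T55_RS16805) were higher at 50 mM and lower at 150 mM, and 10 were the reverse. After median-of-ratios scaling, A2T55_RS04645 and A2T55_RS12915 joined the former, making 5, and 4 tags were the reverse (A2T55_RS04725, A2T55_RS05720, A2T55_RS11850 and A2T55_RS12110). Of these 4, A2T55_RS04725, A2T55_RS05720 and A2T55_RS12110 held 0 fragments at 50 mM and 5, 4 and 6 at 150 mM.

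**Figure D2:**
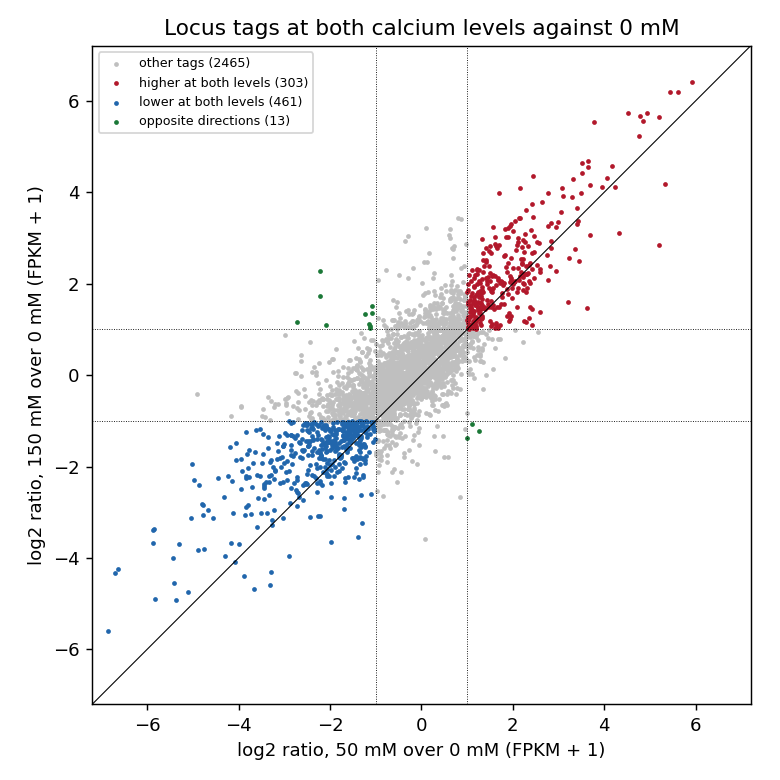
Each point is 1 of 3242 locus tags with a mean of at least 5 FPKM; the horizontal axis is the log2 ratio of 50 over 0 mM and the vertical axis that of 150 over 0 mM, both of FPKM + 1, with dotted lines at 2-fold and a solid line where both are equal. The 303 tags higher (red) and 461 tags lower (blue) at both levels spread along the diagonal, and 13 tags (green) lie in opposite corners; both axes share the library at 0 mM.

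Tags that differed between the libraries were grouped by position when ordered by tag number. Locus tag numbers step by 5 for 3409 of 3421 successive pairs, and their order was taken as gene order, which no annotation used here verifies. Runs of at least 4 successive tags that were all at least 2-fold higher numbered 17 at 50 against 0 mM, 26 at 150 against 0 mM and 22 at 150 against 50 mM, while 1000 shuffles of the order gave at most 4, 8 and 10. Runs of lower tags numbered 60, 20 and 1, against at most 23, 8 and 1 in the shuffles. After median-of-ratios scaling there were 29, 26 and 6 runs of higher tags and 29, 19 and 4 of lower tags. The shuffles used the deposited lists only. Lists after scaling differ in size, so the shuffle limits above do not apply to these counts. The longest run comprised 16 tags, A2T55_RS05940 to A2T55_RS06015, and was at least 2-fold higher throughout at both calcium levels. Its median level was 580 FPKM at 0 mM, 2717 at 50 mM and 2806 at 150 mM, with log2 ratios of 1.53 to 3.50 at 50 mM. A2T55_RS03650 to A2T55_RS03670 comprised 5 tags with a median of 17.7 FPKM at 0 mM, 682 FPKM at 50 mM and 934 at 150 mM. The longest run of lower tags at 50 mM was A2T55_RS01365 to A2T55_RS01420, whose 12 tags had a median of 471 FPKM at 0 mM, 92.2 at 50 mM and 175 at 150 mM, and 9 of them were also at least 2-fold lower at 150 mM. The 10 tags from A2T55_RS02465 to A2T55_RS02510 had medians of 367, 33.1 and 71.6 FPKM. At 150 mM the longest lower run was A2T55_RS01410 to A2T55_RS01460, 11 tags with medians of 1197, 255 and 160 FPKM at 0, 50 and 150 mM. As deposited, 1 run was lower at 150 than at 50 mM, A2T55_RS04645 to A2T55_RS04665, 5 tags with medians of 128, 118 and 33.8 FPKM at 0, 50 and 150 mM. These runs were singled out after the values were seen and lie beside the rule for named tags; they were taken by length, except A2T55_RS03650 to A2T55_RS03670, which is shorter than 4 other runs of higher tags at 50 mM and had a median log2 ratio of 4.94.

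**Figure D3:**
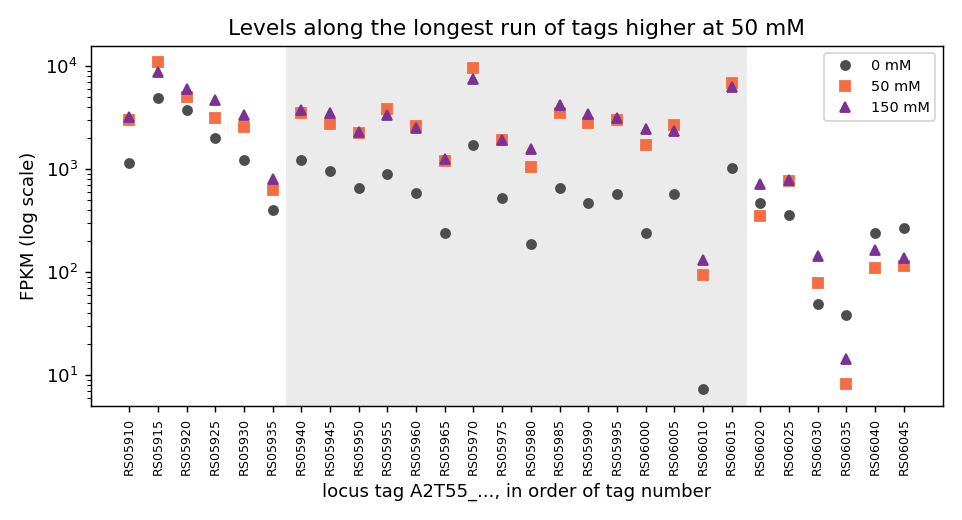
FPKM on a log scale of successive locus tags, in order of tag number, in the libraries at 0 mM (circles), 50 mM (squares) and 150 mM (triangles). The shaded 16 tags, A2T55_RS05940 to A2T55_RS06015, form the longest run higher at 50 mM; their medians were 580, 2717 and 2806 FPKM, and each tag lies above its own level at 0 mM in both calcium libraries.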

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

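The tests in this part were chosen after the ratios had been seen. Among the named tags with a mean of at least 20 fragments, 3 were at least 1.5-fold higher at 50 mM and at least 1.5-fold lower at 150 mM than at 0 mM, opposite directions under the same contrast; the difference between the levels has 1 library on each side and was not tested. The log2 ratios at 50 and 150 mM were 0.84 and -2.66 for A2T55_RS12915, 1.11 and -1.08 for A2T55_RS08920, and 1.25 and -1.23 for A2T55_RS15580. The bound nearest to 1 among their 6 counting intervals was 1.77-fold, and under median-of-ratios and equal-sum scaling the smallest of the 6 ratios, taken in its deposited direction, was 0.73 on the log2 scale. Neither value decides on counting error or library scaling, because the tags were chosen by the size of these ratios, the scalings moved them by less than the 1.5-fold they were chosen by, and the intervals set single libraries against counting noise alone. The calcium level remains an open biological explanation, and it cannot be separated here from anything else that differed between the single cultures, such as growth stage or RNA extraction.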

How the results depend on the processing

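Of 94 counts recomputed under alternatives, 76 stayed within 1.5 times the reported value. This total is no measure of stability, because some outcomes were largely fixed beforehand. A 4-fold rule can only lower counts of tags. The alternative of an interval excluding 1 only drops tags from lists chosen by size on the same fragments. Of the 126 recomputed log2 ratios of the 14 named tags, 21 moved by more than their counting interval reaches on average to either side. None changed direction where the tag met the rule of size. That outcome was fixed beforehand, because the scalings shifted ratios by less than 2-fold and a pseudocount does not turn a sign. Median-of-ratios scaling moved the tags higher at 50 against 0 mM to 593, those higher and lower at 150 against 50 mM to 326 and 184, the runs at 50 against 0 mM to 29 higher and 29 lower, and the runs at 150 against 50 mM to 6 higher and 4 lower; it sets the median tag equal between libraries, so these counts depend on whether the lower median of the 50 mM library is kept. A floor of 20 FPKM left 39 runs lower at 50 against 0 mM, 12 lower at 150 against 0 mM and 12 higher at 150 against 50 mM. A 4-fold rule left 119 higher and 334 lower tags at 50 against 0 mM, 194 and 147 at 150 against 0 mM, 103 and 11 at 150 against 50 mM, and 99 higher and 114 lower at both levels. Equal-sum scaling, a pseudocount of 0.1, no floor, and the 2 alternatives added after the data were seen (a floor of 20 recovered fragments, an interval excluding 1) moved none of the counts of tags by over 1.5 times. Depth limits few calls: a mean under 20 fragments was behind 67 of 1293 tags at 50 against 0 mM, 47 of 1143 at 150 against 0 mM and 56 of 713 at 150 against 50 mM. No paired analysis was possible because each calcium level has 1 library, which also rules out leaving out a replicate; the planned medians of gene lists were not run, as no gene names could be matched.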

Other observations

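In this part, the tests of low counts, of a uniform background and of the neighbouring tags were chosen after the data had been seen; leaving out the most abundant tags was chosen before its result was.

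Against 0 mM, tags that stood furthest apart lay beside one another more often than in random sets. Of the 20 highest tags with a mean of at least 20 fragments, 11 at 50 against 0 mM and 12 at 150 against 0 mM had a directly adjacent tag among the 20, against at most 4 and 6 in 1000 random sets. Among the 20 lowest tags the numbers were 11 and 7, against at most 6 and 4. At 150 against 50 mM they were 6 of the 20 highest (at most 6 in random sets) and 5 of the 20 lowest (at most 4). A2T55_RS02740 and A2T55_RS02750, both among the named tags, are separated by a single tag number, A2T55_RS02745, which stood at 20.7 FPKM at 0 mM, 584 at 50 mM and 812 at 150 mM.

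As deposited, 22 runs of at least 4 successive tags were at least 2-fold higher at 150 than at 50 mM, which became 6 after median-of-ratios scaling. The 3 longest as deposited, taken by length after the values were seen, differed in their levels at 0 mM. A2T55_RS06540 to A2T55_RS06585, 10 tags, had medians of 39.3 FPKM at 0 mM, 26.4 at 50 mM and 81.7 at 150 mM. A2T55_RS04420 to A2T55_RS04455, 8 tags, had medians of 13.7, 48.5 and 117 FPKM at 0, 50 and 150 mM; at 50 against 0 mM, 3 of these tags were at least 2-fold higher and 2 at least 2-fold lower. A2T55_RS13455 to A2T55_RS13480, 6 tags, stood lower at 50 mM and nearer to the level at 0 mM at 150 mM, with medians of 200, 24.2 and 152 FPKM.

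A pattern to follow up is that tags with neighbouring numbers moved together. Pearson's r across tags between the log2 ratios of adjacent tags was 0.42 at 50 against 0 mM, 0.43 at 150 against 0 mM and 0.30 at 150 against 50 mM, where shuffled orders reached at most 0.056. A broad trend along the chromosome is argued against by tags 50 places apart. Their r was -0.025 at 50 against 0 mM, -0.017 at 150 against 0 mM and 0.0075 at 150 against 50 mM. Each value lay inside the range of its shuffles. Taken with its sign, the ratio to r of adjacent tags was at most 0.025. Reads shared between adjacent genes are argued against as the whole cause, because r between tags 2 places apart (0.13 to 0.27) exceeded the highest shuffle by at least 0.077. A hypothesis is that the runs are blocks of genes transcribed together: adjacent members of the runs at 50 against 0 mM differed in FPKM at 0 mM by a median of 1.05 on the log2 scale, 0.547 times the difference between random pairs of tags called in the same direction (1.93, and no lower than 1.56 in 1000 draws), which is consistent with it, though genes of like function can also lie together without sharing a transcript.

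A second pattern is the lower median tag of the 50 mM library. It was not the work of a few abundant tags alone: without the 21 tags that were among the 10 most abundant of any library, which held 12.0%, 18.2% and 10.4% of the fragments at 0, 50 and 150 mM, the median log2 ratio of 50 over 0 mM was -0.26 in place of -0.36. Low counts are argued against, since it was -0.45 among 1807 tags with a mean of 100 to 1000 fragments, although it was 0.08 among 809 tags with at least 1000. A uniform background of fragments, such as genomic DNA, that was lower in the 50 mM library is argued against as the whole cause: the 8.67 FPKM that would bring the lowest of 4 bins of tags by mean FPKM to 0 left the next bin at -0.37. What stays open includes a real shift of RNA levels towards the more abundant genes at 50 mM. Other differences of that one culture, such as growth stage, or of its library preparation also stay open. With 1 library per level these are not separated.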
